A study of Mus musculus with 11 samples.

How the data were processed

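RNA abundance was measured on 11 one-colour Affymetrix whole mouse genome arrays, 1 per sample. The samples were mouse trophoblast stem cells, the precursors of the placental trophoblast, grown with 10 ng/ml FGF4, heparin and medium conditioned by embryonic fibroblasts, per the labels' protocols. Cells were harvested after 0, 0.5, 2, 6 or 24 h in 400 mM sorbitol, a sugar alcohol that raises the osmolarity of the medium. Biotin-labelled cRNA was made from 6 µg of total RNA by the standard Affymetrix protocol, per the labels. One label field names embryos as the source while the titles and protocols name the stem cells, and the latter were followed. Groups were taken from the times in the sample titles.

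The deposited table holds linear intensities, 1 value per probe set and array. How the authors summarised, scaled and normalised the probe sets is not given in the sources used here. In every array the lowest value was exactly 100, and 71.6% to 74.9% of the probe sets lay at that floor. The median over all probe sets was therefore 100 on every array and carried no information on scaling. The highest values lay between 10767 and 12702. Over the probe sets tested, the median intensity ranged from 225 to 275 between arrays. A value at the floor is an upper bound, and a change from or to it is understated. The number of arrays, not a depth of counting, limits the precision. All 11 columns belonged to a sample.

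The table holds 45101 probe sets, of which 64 Affymetrix control probe sets were left out of the tests. Gene symbols came from the platform annotation and were checked against a RefSeq gene table through Entrez identifiers, where 34754 probe sets matched and none had another symbol. Of the 45037 remaining probe sets, 34945 had 1 symbol, 932 had several and 9160 had none listed. A probe set was tested when at least 2 of the 11 arrays exceeded the 40th percentile of all values, which was the floor of 100. This left 14023 probe sets, 12832 of them with 1 symbol, 428 with several and 763 with none listed. A gene that stayed at the floor was not tested and is not among the measured members of a list. A probe set at the floor at all times before 24 h was tested only if both 24 h arrays exceeded the floor. Shares of members that rose at 24 h are thus partly fixed by the filter. The same holds for falls of probe sets above the floor at 0 h alone. A gene was represented by its tested probe set of highest mean among those listing that gene alone, which gave 8140 genes. No gene was named from a probe set with several symbols. A named gene may have other tested probe sets that did not pass the test, and these are given for some genes only.

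Values were analysed as log2(intensity + 16), so log2 changes of dim probe sets are smaller than the changes in intensity. No further normalisation was applied, by a rule that compared the medians of all probe sets, which here all lay at the floor. The medians of the tested probe sets did differ, and quantile normalisation and median centring were run as alternatives. A linear model with 1 mean per time was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with empirical Bayes moderation and a mean-variance trend, 6 residual degrees of freedom and 2.55 prior degrees of freedom. Each time was compared with 0 h, and 4 differences between times were tested in the same fit. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. A moderated F test over the 4 comparisons with 0 h covered the time course as a whole. Where every array of a group lay at the floor, the ratio of the geometric mean intensities is given as a lower bound ("at least N-fold") with the adjusted p of the fit.

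Gene lists were tested with camera, which compares a list with all other genes, with a preset inter-gene correlation of 0.01 and adjustment over all lists and the 4 times. The same test with an estimated correlation and fry, which asks whether the members move 1 way on balance, were run beside it. The 22 lists, of 374 genes, covered osmolyte and ion transport, immediate-early genes, FGF and ERK feedback, NF-kB and cytokine genes, markers of trophoblast stem cells, giant cells, spongiotrophoblast and syncytiotrophoblast, p53 targets, the unfolded protein and integrated stress response, heat shock and chaperones, oxidative stress and metal response, DNA replication, mitosis, cholesterol synthesis, glycolysis and hypoxia, the respiratory chain, ribosome biogenesis, actin and SRF targets, and markers of fibroblasts, pluripotent epiblast and extraembryonic endoderm as other cell types. The sample groups, tests and lists were fixed before the data were examined. The rule for named genes was fixed with them. It named, at each time, the 7 largest rises and the 7 largest falls past the test in which every array lay beyond both arrays at 0 h, up to 3 members of each list with a camera call or at least 3 members past the test, and 12 panel genes whatever their p. For differences between times it named the 3 largest each way. Panel genes Prl3d1 and Ccnb1 had no probe set listing them alone and are not reported here.

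Principal components of the tested probe sets showed a division of the arrays other than time. The first component held 40.0% of the variance and separated the 24 h arrays from the rest. The second held 35.7% and split the arrays of 4 of the 5 times. By its sign, replicate 1 at 0 h, replicates 1 and 2 at 0.5 h, replicate 1 at 2 h and replicate 1 at 24 h formed batch A, and the other 6 arrays formed batch B, which held both 6 h arrays. The hybridisation control creX, which was left out of the tests, averaged 7338 to 9379 on batch A and 5493 to 6691 on batch B, without overlap. Batch was added as a block in a second fit (5 residual degrees of freedom), chosen after the data were seen, and its counts and the changes within each batch are given beside the main ones. The labels name no batch, but the split also follows the order of the sample records, with batch A first. Because the batches were derived from the values tested, the block removes spread by construction and its p-values may be too small. Changes within a batch come from the arrays that gave the calls, so a shared direction is no independent support. The 2 arrays at 6 h were far more alike than any other pair (r = 0.998 across probe sets, SD of the log2 differences 0.0906, against 0.162 for the next closest pair and 0.266 to 0.414 for the other pairs of 1 time). Their values were not identical, and they were kept as 2 samples. Counts of probe sets are also given with their mean as 1 sample. The labels say that RNA was isolated 2 or 3 times per time point and not whether from separate cultures, so the p-values measure only the spread between these samples.

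Scripts were tested on simulated arrays with 200 changed probe sets among 14023. Without a batch effect, 80% to 86% of the 1 log2 changes and 82% to 89% of the 2 log2 changes were recovered over the 4 comparisons with 0 h, with 5 to 11 false calls. With a simulated batch effect the same fit recovered 37% to 47% and 66% to 71%, with no false calls among unchanged probe sets. The alternatives tried were quantile normalisation, median centring, offsets of 1 and 64, no filter on low values, the variance prior without trend or made robust, array weights, only the arrays compared, the replicate number as a block, the mean of a gene's probe sets, a 2-fold threshold and leaving out each array in turn. Added after the data were seen were the batch block, a minimum mean intensity of 200 and the 6 h arrays averaged into 1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.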

Results

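Gene expression was followed through 24 h of hyperosmolar stress in cultured mouse trophoblast stem cells, which give rise to the trophoblast of the placenta. The question was how the transcript profile changes with time in 400 mM sorbitol. No culture without sorbitol was sampled after 0 h. Changes from 0 h therefore cannot be told apart from effects of time in culture. There were 2 arrays each at 0, 2, 6 and 24 h and 3 at 0.5 h, and each carried 11315 to 12775 probe sets above the intensity floor of 100. Values are intensities as mean ± SD over the arrays of a time (n = 2, or 3 at 0.5 h), and changes are log2 differences from 0 h on the log2(intensity + 16) scale.

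After 0.5 h the transcripts that fell included small nucleolar RNA host genes, with 5 of the 34 lower probe sets. Snhg3, a host gene whose introns carry small nucleolar RNAs, fell from 628 ± 319 to 127 ± 46.0 (log2 change -2.13, adjusted p = 0.0441). Snhg4, of the same kind, fell from 369.8 ± 45.1 to 132 ± 39.9 (-1.41, adjusted p = 0.0329). The long non-coding RNA Dancr fell at least 2.52-fold (adjusted p = 0.00936), and a probe set for the ribosomal protein gene Rpl12 at least 2.07-fold (adjusted p = 0.00205). Irak1, a kinase of interleukin-1 receptor signalling, fell at least 1.34-fold from 134 ± 7.54 (adjusted p = 0.0365). The 1 other tested Irak1 probe set did not pass the test. Among probe sets that do not represent their gene, chosen after their values were seen, 2 probe sets of Gas5, another small nucleolar RNA host, fell (-2.67 and -2.20, adjusted p = 0.000869 and 0.000304). The brightest Gas5 probe set, at 2333 in untreated cells, had a log2 change of -0.26 (adjusted p = 1). Probe sets for Taf1d, a subunit of the RNA polymerase I initiation factor, and Tardbp, an RNA-binding protein, lay at the floor on all 3 arrays (at least 5.82-fold and at least 2.64-fold lower, adjusted p = 0.000362 and 0.000304). Their genes' brighter probe sets changed by -0.03 and -0.08 (adjusted p = 1 for both). The osmolyte transporter gene Slc5a3, which imports myo-inositol, stood at 185 ± 33.2 against 215 ± 44.6, and the taurine transporter gene Slc6a6 at 1450.4 ± 95.6 against 1499 ± 0.785, neither past the test (log2 changes -0.21 and -0.05, adjusted p = 1 for both).

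In all, the count of probe sets changed at 0.5 h against 0 h was 34 of 14023, each of them lower, and 440 had an unadjusted p under 0.05 (limma). The 34 included 14 at the floor on every 0.5 h array, and 5 represented a single gene. All 34 fell in both batches, which selecting calls from these same arrays favours, and with batch as a block 67 passed, 4 higher and 63 lower. By camera 3 gene lists lay higher, with medians of 0.10 for mitosis (adjusted p = 0.000598; adjusted p = 0.601 with an estimated correlation), 0.11 for glycolysis and hypoxia (adjusted p = 0.00671; adjusted p = 0.814 with an estimated correlation) and 0.06 for the respiratory chain (adjusted p = 0.00585; adjusted p = 0.569 with an estimated correlation), but no member passed the test alone. All 3 calls were lost without 0 h replicate 2 or without 0.5 h replicate 1. The glycolysis call did not pass with batch as a block (adjusted p = 0.0902). The count was 70 without 0 h replicate 1, 20 without 0.5 h replicate 2 and 54 without 24 h replicate 1 or 24 h replicate 2, and 23 with the 6 h arrays averaged into 1. It was 22 after median centring, 0 with a minimum mean intensity of 200 (limma, 165 at an unadjusted p under 0.05), under which 1 of the 34 was tested, and 0 when only the arrays compared entered the fit (limma, 458 at an unadjusted p under 0.05).

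**Figure D1:**
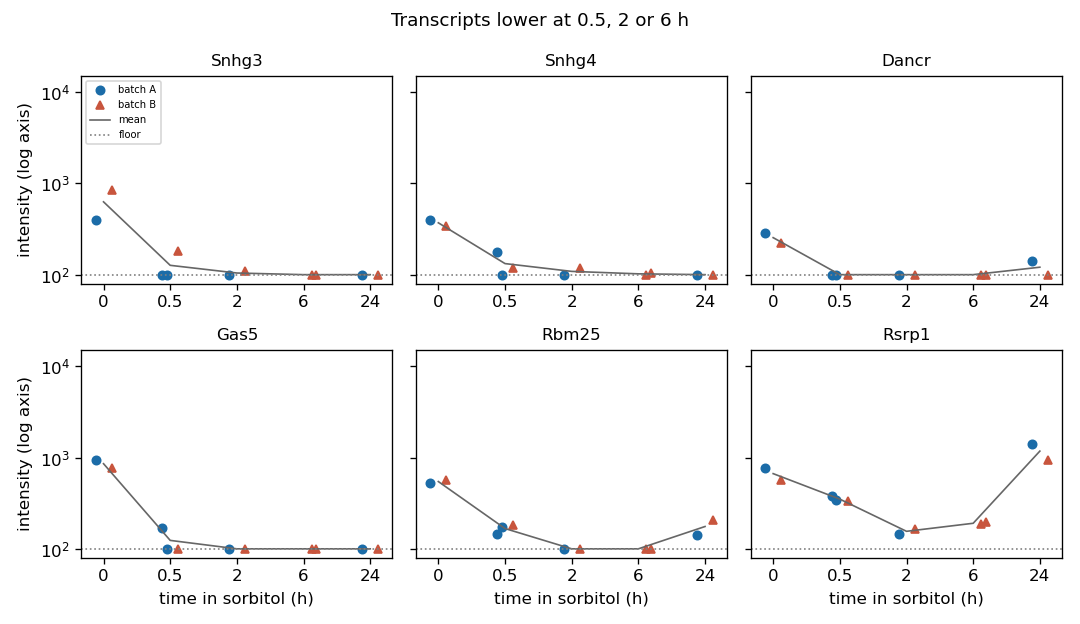
Intensity on a log axis against time in sorbitol (h) for probe sets of 6 genes, with points for arrays of batch A (circles) and batch B (triangles), a line through the means and the floor of 100 dotted. Gas5 and Rbm25 are shown by a probe set that is not their gene's brightest, and the Gas5 probe set fell from 856 ± 129 to the floor by 2 h.

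After 2 h 6 of 18 small nucleolar RNA host probe sets were lower than at 0 h. Of 23 histone probe sets 4 had risen, as had the Sgce probe set. Sgce, an imprinted gene for a sarcoglycan, rose from 174 ± 49.8 to 684 ± 277 (log2 change 1.85, adjusted p = 0.0404). H2bc22, which encodes a histone H2B, rose from 241 ± 39.6 to 677 ± 66.0 (1.44, adjusted p = 0.00735), measured by a probe set marked by the manufacturer as open to cross-hybridisation. At 0.5 h it read 331 ± 30.6 (log2 change 0.44, adjusted p = 1). With the batch block, whose p-values may be too small, the adjusted p at that time was 0.0424. Of the 5 probe sets that rose, the other 3 each listed 11 to 13 histone genes. Snhg3 and Snhg4 fell (-2.33 and -1.63, adjusted p = 0.0309 and 0.0156). Dancr stayed at the floor (at least 2.52-fold lower, adjusted p = 0.0126), and Snhg5 fell from 719 ± 44.7 to 254 ± 1.08 (adjusted p = 0.0029). Rsrp1, which encodes an arginine- and serine-rich protein, fell from 666 ± 139.9 to 156 ± 12.3 (-1.98, adjusted p = 0.00536). Of 2 other tested Rsrp1 probe sets, 0 fell past the test at 2 h or at 6 h, and 0 had the opposite sign. Pnpt1, which encodes polynucleotide phosphorylase of mitochondria, fell by 1.35 (adjusted p = 0.0309), and 4930447C04Rik fell by 1.34 (adjusted p = 0.0373). Beside these changes the 18S ribosomal RNA control probe set at the 3' end read 10208 ± 222, against 401 ± 263 at 0 h.

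The count of probe sets changed at 2 h against 0 h was 60, with 5 higher and 55 lower (limma, 531 at an unadjusted p under 0.05), and 34 of the lower ones were at the floor on both 2 h arrays. All 60 moved the same way in both batches, which the selection again favours, and the batch block gave 143. Camera called none of the 20 measured lists shifted (none at an unadjusted p under 0.05 either, and none by fry). The immediate-early list, which responds to many stresses within an hour in other settings, had a median of 0.02, and Fos and Egr1 read 371 ± 65.7 and 303 ± 98.5 against 341 ± 56.7 and 268 ± 107 (adjusted p = 1 for both). The count was 22 without 2 h replicate 1, 33 without 6 h replicate 1 or 6 h replicate 2, 33 with the 6 h arrays averaged into 1, and 10 with a minimum mean intensity of 200. With only the arrays compared it was 0 (limma, 379 at an unadjusted p under 0.05). Lists shifted numbered 2 without 0 h replicate 1 and 1 without either 2 h array.

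After 6 h H2bc22 had risen further. It reached 2220.2 ± 88.7 (log2 change 3.13, adjusted p = 0.000122), and H2ac19, a histone H2A gene at the floor in untreated cells, stood at 513 ± 7.64, at least 5.13-fold higher (adjusted p = 0.0141). Both probe sets are marked as open to cross-hybridisation. Sgce stood at 741 ± 73.6 (2.02, adjusted p = 0.0214). The immune checkpoint ligand gene Cd276 rose from 158 ± 3.32 to 377 ± 2.55 (adjusted p = 0.0335), and the stress-inducible Gadd45b rose from 467 ± 25.2 to 776 ± 39.1 (0.71, adjusted p = 0.0455). A second Gadd45b probe set of similar brightness did not show this rise (457 ± 60.8 to 485 ± 0.41, log2 change 0.09, adjusted p = 0.981). Snhg3 lay at the floor (at least 5.86-fold lower, adjusted p = 0.0227), and Snhg4, Rsrp1, Snhg5 and Pnpt1 fell (-1.70, -1.71, -1.30 and -1.23, adjusted p = 0.0108, 0.0108, 0.004 and 0.0405). 4930447C04Rik was at least 2.88-fold lower (adjusted p = 0.0243), and Erdr1, also open to cross-hybridisation, fell from 1614 ± 100.2 to 662 ± 43.1 (adjusted p = 0.00487). The 18S control read 10850 ± 251 at this time.

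The count of probe sets changed at 6 h against 0 h was 79, 13 higher and 66 lower (limma, 1027 at an unadjusted p under 0.05), and 7 of the 13 listed histones. The 5 genes that rose by the probe set representing them were the 5 named above. Of the immediate-early list, 1 of 24 members rose, Gadd45b (2 adjusted over the list alone), the median was 0.29, and camera called it higher (adjusted p = 0.0015; adjusted p = 0.622 with an estimated correlation). The mitosis list lay lower, with a median of -0.20 (adjusted p = 0.0094; adjusted p = 0.809 with an estimated correlation; adjusted p = 0.346 with the batch block). Both arrays at 6 h lay in batch B, where all 79 moved the same way against the 0 h array of that batch. The selection of calls favours this too, and the batch block gave 248. The count was 49 without 0 h replicate 2, 18 without 6 h replicate 1, 22 without 6 h replicate 2, 138 without 24 h replicate 1, 139 without 24 h replicate 2, 19 with the 6 h arrays averaged into 1, and 19 with a minimum mean intensity of 200. With only the arrays compared it was 0 (limma, 1937 at an unadjusted p under 0.05).

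**Figure D2:**
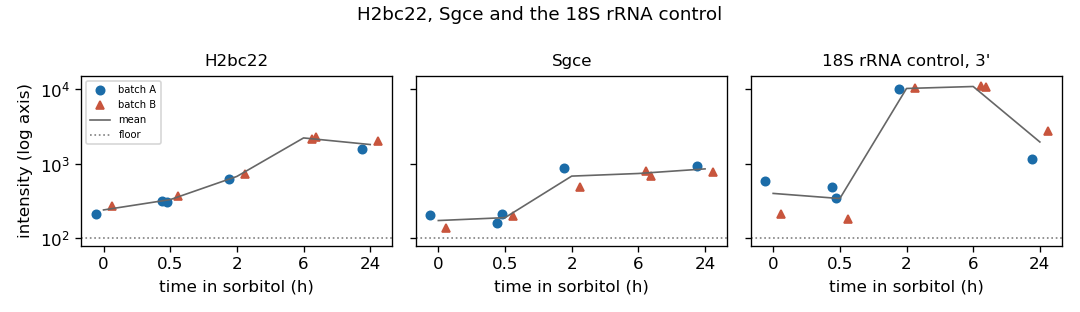
Intensity on a log axis against time in sorbitol (h) for H2bc22, Sgce and the 18S ribosomal RNA control probe set at the 3' end, with points for arrays of batch A (circles) and batch B (triangles), a line through the means and the floor of 100 dotted. H2bc22 stood at 2220.2 at 6 h and 1811 at 24 h, and the 18S control at 10850 and 1960.

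After 24 h many more probe sets had changed, and immediate-early genes were among the rises. The transcription factor genes Klf4 and Egr1 rose from 102 ± 3.20 to 973 ± 109 and from 268 ± 107 to 1888 ± 1140 (log2 changes 3.06 and 2.66, adjusted p = 1.03e-05 and 0.0098). Ccn2, a secreted matrix-associated factor, rose from 228 ± 86.6 to 1912 ± 547 (3.00, adjusted p = 0.00463). Of the 24 measured immediate-early genes 14 rose (15 adjusted over the list alone), among them Fos (1.66, adjusted p = 0.00359) and Atf3 (2.08, adjusted p = 0.000595), and the median was 1.48 (camera adjusted p = 1.03e-09; adjusted p = 0.312 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, rose from 107 ± 10.1 to 742 ± 379 (adjusted p = 0.00113). The cytokine gene Lif rose at least 3.96-fold (adjusted p = 0.00129), and Csf1 rose by 1.19 (adjusted p = 0.0499). These were the 3 of 7 measured NF-kB and cytokine genes that rose (3 adjusted over the list alone; camera adjusted p = 0.004; adjusted p = 0.312 with an estimated correlation). Of 2 other tested Csf1 probe sets, 1 had the opposite sign and 0 rose past the test. At this time the Actb 3' to 5' signal ratio, a measure of RNA integrity, was 1.33 ± 0.0395 against 1.19 ± 0.0374 at 0 h, and that of Gapdh 1.15 ± 0.241 against 0.911 ± 0.0418. These ratios stand beside all gene groups reported at 24 h.

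Some genes of the stress response pathways rose as well, while others fell or did not pass the test. Of 18 measured genes of the unfolded protein and integrated stress response 8 rose and 2 fell (9 and 2 adjusted over the list alone), led by Ppp1r15a, which directs dephosphorylation of eIF2α (162 ± 28.8 to 1297 ± 49.1, adjusted p = 0.000494), and the transcription factor genes Ddit3 (2.29, adjusted p = 2.15e-05) and Cebpb (1.72, adjusted p = 0.00593). The 2 that fell were Asns and Psat1, enzymes of asparagine and serine synthesis. The median was 0.46 (camera adjusted p = 0.00108; adjusted p = 0.312 with an estimated correlation). Among 15 p53 targets 6 rose and Zmat3 fell (7 and 1 adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a rose from 413 ± 63.7 to 2049 ± 288 (adjusted p = 0.000469), with Plk2 at 1.82 (adjusted p = 0.00875) and the pro-apoptotic Bbc3 at 1.17 (adjusted p = 0.0043). The list median was 0.55 (camera adjusted p = 0.0015; adjusted p = 0.569 with an estimated correlation). Of 16 heat shock genes 6 rose and Hsph1 fell (6 and 4 adjusted over the list alone). The inducible Hsp70 genes Hspa1a and Hspa1b rose at least 5.54-fold and from 688 ± 146 to 3299 ± 81.6 (adjusted p = 1.03e-05 and 0.000741), and Cryab by 1.82 (adjusted p = 0.0105). The list itself was not shifted (camera adjusted p = 0.077). Of 9 osmolyte and ion transport genes Sgk1, a kinase that regulates ion channels, and Slc5a3 rose (2.14 and 1.16, adjusted p = 0.0035 and 0.0128), the ion cotransporter gene Slc12a2 fell by 0.60 (adjusted p = 0.0429), and the counts adjusted over the list alone were 2 and 1 (camera adjusted p = 0.351). Of 2 other tested Slc12a2 probe sets, 1 had the opposite sign and 0 fell past the test. Slc6a6 stood at 1278 ± 198 against 1499 ± 0.785 (adjusted p = 0.21).

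**Figure D3:**
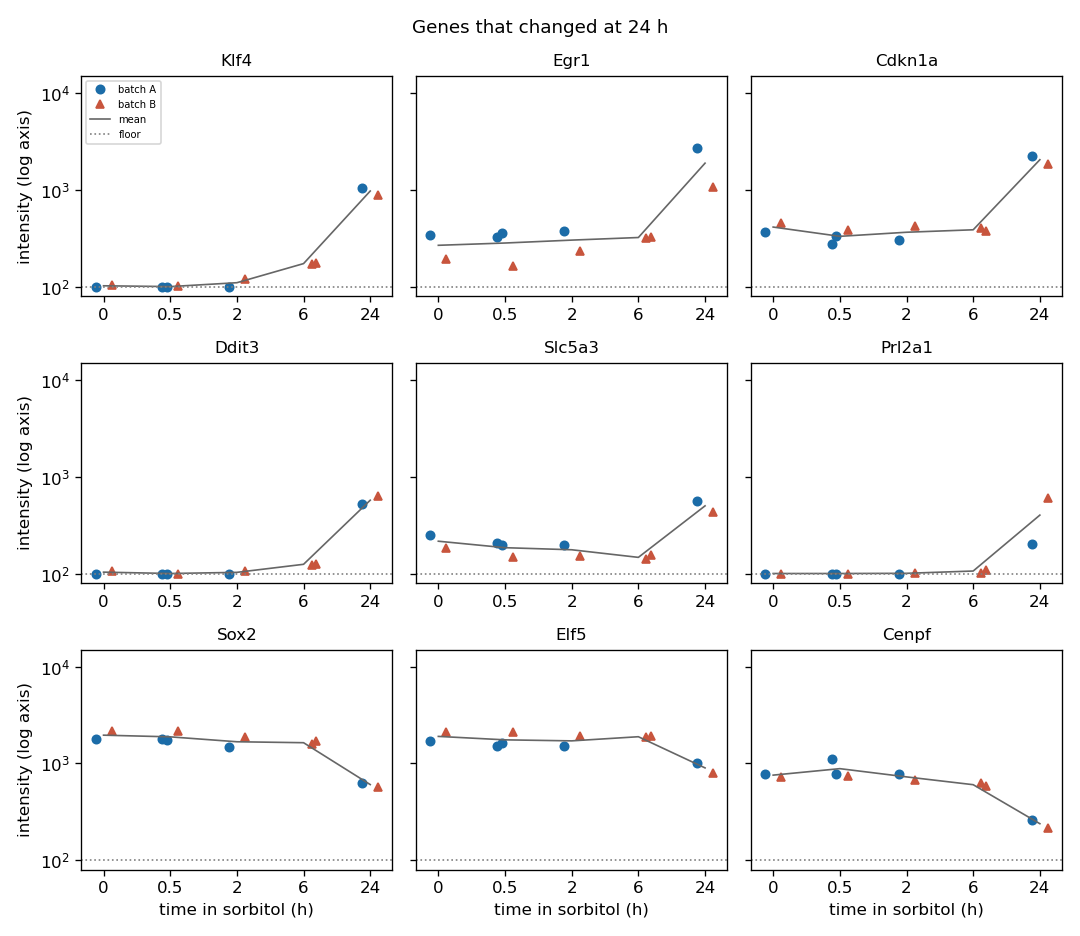
Intensity on a log axis against time in sorbitol (h) for 9 genes that changed at 24 h, with points for arrays of batch A (circles) and batch B (triangles), a line through the means and the floor of 100 dotted. Cdkn1a stood at 387 at 6 h and 2049 at 24 h, and Sox2 fell from 1959 at 0 h to 605 at 24 h.

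Some markers of the undifferentiated trophoblast fell and some giant cell markers rose at 24 h. The stem cell transcription factor genes Sox2, Esrrb and Elf5 fell from 1959 ± 267 to 605 ± 41.0, from 632 ± 61.1 to 286 ± 58.0 and from 1902 ± 297 to 899.5 ± 143 (adjusted p = 0.000423, 0.0124 and 0.00877). Of 14 stem cell markers 4 fell and Ets2 rose (4 and 1 adjusted over the list alone), but without a list call (camera adjusted p = 0.139). Cdx2 read 360.0 ± 64.9 against 630.3 ± 359 (adjusted p = 0.417, and 0.0277 with the batch block, which may be too small), and Id2 3077 ± 884 against 3720.3 ± 36.4 (adjusted p = 0.305). Of 7 measured giant cell markers 4 rose (5 adjusted over the list alone). Any listed marker that stayed at the floor was not tested, which favours rises in this count. Bhlhe40 rose from 346 ± 147 to 1698 ± 378, the prolactin family gene Prl2a1 at least 3.49-fold and Cdkn1c by 0.98 (adjusted p = 0.0337, 0.0178 and 0.0213). The giant cell median was 0.98 (camera adjusted p = 0.00671; adjusted p = 0.569 with an estimated correlation). Hand1 read 2511 ± 863 against 2350.5 ± 732 (adjusted p = 0.903). The FGF feedback genes Spred2, Etv5 and Spred1 fell (-1.62, -1.22 and -1.02, adjusted p = 0.0314, 0.0459 and 0.0116), and 5 of the 10 genes of that list fell (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.119). Of the other lineages, Flt1 rose among 4 spongiotrophoblast markers and Dlx3 among 7 syncytiotrophoblast markers (camera adjusted p = 0.439 and 0.351). Among genes listed as markers of other cell types, 3 of 5 pluripotent epiblast genes fell, Zfp42, Dppa4 and Utf1 (-0.86, -0.77 and -0.73, adjusted p = 0.0275, 0.00558 and 0.0168; 3 adjusted over the list alone; camera adjusted p = 0.119), while none of 14 fibroblast or 12 extraembryonic endoderm markers was represented among the probe sets tested. Zfp42, Dppa4 and Utf1 read 1450, 1174 and 705 at 0 h, and which cells carried these transcripts was not measured.

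Most mitosis genes and fewer genes of DNA replication, cholesterol synthesis and ribosome biogenesis fell at 24 h. Of 23 mitosis genes 17 fell (19 adjusted over the list alone), among them the kinetochore genes Cenpf, Cenpe and Bub1b (-1.61, -1.57 and -1.53, adjusted p = 0.00176, 0.00144 and 0.00113), and the median was -0.86 (camera adjusted p = 7.40e-10; adjusted p = 0.312 with an estimated correlation). Of 2 other tested Cenpf probe sets, 0 fell past the test and 0 had the opposite sign. Of 23 genes of DNA replication 11 fell (14 adjusted over the list alone), such as Cdc6, which loads the replicative helicase, and the polymerase gene Pole (-1.05 and -1.03, adjusted p = 0.00216 and 0.00259), while the cyclin gene Ccne2 rose from 208 ± 3.67 to 526 ± 156 (adjusted p = 0.00747). That list had a median of -0.46 (camera adjusted p = 0.000316; adjusted p = 0.312 with an estimated correlation). In cholesterol synthesis 4 of 16 genes fell (5 adjusted over the list alone), with Idi1, Fdps and Msmo1 at -0.98, -0.80 and -0.69 (adjusted p = 0.0241, 0.017 and 0.0208; camera adjusted p = 0.00852; adjusted p = 0.601 with an estimated correlation). In ribosome biogenesis 5 of 20 fell (6 adjusted over the list alone), with Polr1b, a subunit of RNA polymerase I, at -1.13, Wdr12 at -0.55 and Gar1 at -0.52 (adjusted p = 0.0079, 0.00673 and 0.0224; camera adjusted p = 0.00671; adjusted p = 0.569 with an estimated correlation). The remaining lists had no camera call. Hmox1 alone rose among 9 oxidative stress genes, Ndufs3 alone fell among 22 genes of the respiratory chain, and the glycolysis and actin lists had medians of 0.02 and 0.22 (camera adjusted p = 0.484, 0.819, 0.783 and 0.286).

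**Figure D4:**
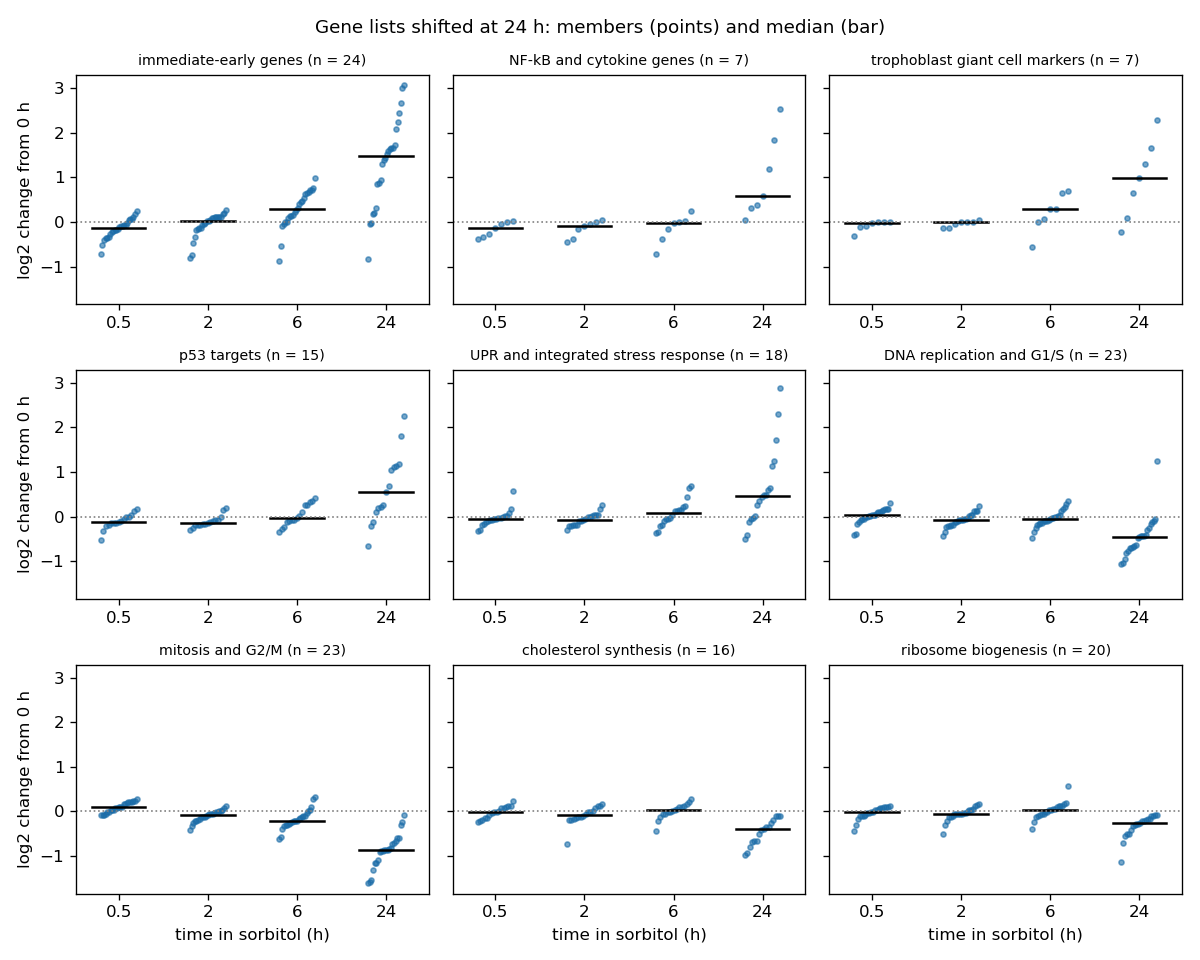
Log2 change from 0 h (points, 1 per gene) and median (bar) at 0.5, 2, 6 and 24 h for the 9 lists with a camera call at 24 h, members sorted by value within each time. The immediate-early median was 0.29 at 6 h and 1.48 at 24 h, and the mitosis median -0.20 and -0.86.

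Other genes also changed at 24 h. Gadd45g, of the growth arrest family, rose from 133 ± 37.3 to 1688 ± 354 (3.52, adjusted p = 8.36e-05). The predicted gene Gm6958 rose at least 9.78-fold (adjusted p = 3.92e-06, a probe set open to cross-hybridisation), and H2bc22 stood at 1811 ± 318 (2.83, adjusted p = 5.33e-05). Snhg3 remained at the floor, at least 5.86-fold lower (adjusted p = 0.00352). The chromatin remodeller gene Atrx fell from 1009 ± 89.7 to 209 ± 25.8 (adjusted p = 8.63e-05), Utp3, of the small ribosomal subunit processome, from 1510.2 ± 495 to 332 ± 36.5 (adjusted p = 0.00438), and Cpne3 from 2937 ± 529.9 to 798 ± 33.3 (adjusted p = 0.000391). AU020206 and Zbtb44 fell (-1.91 and -1.86, adjusted p = 7.99e-05 and 0.000218), and 4930428B01Rik fell at least 3.99-fold (adjusted p = 0.0185). The count of probe sets changed at 24 h against 0 h was 2304, 1073 higher and 1231 lower (limma, 4314 at an unadjusted p under 0.05), of which 621 changed at least 2-fold. The split was 1169 higher and 1100 lower after median centring, and 1276 and 1267 after quantile normalisation. All 2304 moved the same way in both batches, and the batch block gave 5266. The medians of the 9 shifted lists also had the same sign in batch A and batch B, such as 1.86 and 1.21 for the immediate-early list and -0.83 and -0.87 for mitosis. The calls came from these same arrays, so a shared direction was largely fixed by the selection and is no independent support. The count was 1231 without 0 h replicate 1, 1099 without 0 h replicate 2, 1489 without 6 h replicate 1, 1495 without 6 h replicate 2 and 1491 with the 6 h arrays averaged into 1. With only the 4 arrays compared, which leave 2 residual degrees of freedom, it was 0 (limma, 2996 at an unadjusted p under 0.05).

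Differences between times were tested to ask when the changes from 0 h developed. A probe set listing 11 histone genes was the only one of the probe sets differing between 2 h and 0.5 h (log2 difference 1.11, adjusted p = 0.047). H2bc22 rose further from 2 h to 6 h by 1.69 (adjusted p = 0.019). It was 1 of the 6 probe sets differing between 6 h and 2 h, all higher at 6 h, which included 3 more histone probe sets, 1 for the dynactin gene Dctn4 and 1 with no symbol listed. After median centring that split was 4 higher and 1 lower. The Dctn4 probe set does not represent its gene, whose brighter probe set changed by 0.16 at 6 h against 0 h (adjusted p = 0.953). From 6 h to 24 h Gadd45g, Tnfaip3 and Gm6958 rose by 2.65, 2.56 and at least 9.78-fold (adjusted p = 0.000392, 0.00133 and 3.92e-06). Utp3, Cpne3 and Kntc1, a kinetochore gene, were lower (-2.19, -1.87 and -1.58, adjusted p = 0.00507, 0.000438 and 0.0137). Kntc1 had read higher at 0.5, 2 and 6 h than at 0 h. Its values at 24 h (212 and 154) lay near those at 0 h (198 and 150). Against 0.5 h, Gadd45g, Ccn2 and the serpin gene Serpinb9g were higher at 24 h by 3.45, 3.40 and 3.14 (adjusted p = 4.41e-05, 0.00148 and 0.00241). Utp3, Atrx and Cenpf were lower (-2.22, -1.91 and -1.80, adjusted p = 0.00168, 8.44e-05 and 0.000549).

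Immediate-early genes already lay higher as a list at 6 h than at 2 h by camera, with a median difference of 0.37 (adjusted p = 0.000519; adjusted p = 0.343 with an estimated correlation), and at 2 h than at 0.5 h (0.12, adjusted p = 0.0344; adjusted p = 0.604 with an estimated correlation). Mitosis genes lay lower at 2 h than at 0.5 h (-0.21, adjusted p = 2.07e-05; adjusted p = 0.309 with an estimated correlation) and at 6 h than at 2 h (-0.10, adjusted p = 0.000746; adjusted p = 0.371 with an estimated correlation). Glycolysis genes lay lower in the same steps (-0.16 and -0.09, adjusted p = 0.049 and 0.0148; adjusted p = 0.678 and 0.617 with an estimated correlation), and actin and SRF targets higher from 2 h to 6 h (0.23, adjusted p = 0.0114; adjusted p = 0.608 with an estimated correlation). No member of these lists passed the test alone in these steps. Both 6 h arrays lay in batch B, while those at 2 h and 24 h were split between the batches. List differences of 6 h from 2 h or 24 h therefore mix batch with time. The lists at 24 h against 6 h and 0.5 h are given with the closing observations.

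The numbers of probe sets differing between 24 h and 6 h and of probe sets differing between 24 h and 0.5 h were 1581 (903 higher, 678 lower) and 3094 (1535 higher, 1559 lower; limma). With the batch block they were 3910 and 5820, and 7 probe sets passed between 2 h and 0.5 h and 10 between 6 h and 2 h. The first fell to 219 without 6 h replicate 1, to 220 without 6 h replicate 2 and to 213 with the 6 h arrays averaged into 1, and the second to 2005 without 0.5 h replicate 1, to 2197 with the 6 h arrays averaged into 1 and to 1037 with only the arrays compared. The single call between 2 h and 0.5 h was lost without any 1 of the 3 arrays at 0.5 h, 2 h replicate 1, 6 h replicate 1 or 6 h replicate 2. The 6 calls between 6 h and 2 h became 23 and 24 without 24 h replicates 1 and 2, and 1 to 3 without any 1 of the other 9 arrays. By the F test over the time course, probe sets changed at any time numbered 1444 (585 without 6 h replicate 1, 586 without 6 h replicate 2, 948 without 24 h replicate 2, 579 with the 6 h arrays averaged into 1, 4320 with the batch block), and 1277 of them (88.4%) had their largest change at 24 h.

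Early falls such as those of Snhg3, Snhg4 and Dancr were shared between times. All 34 probe sets lower at 0.5 h were also lower at 2 h and at 6 h, where independent lists would share 0.133 and 0.160. Of the 69 probe sets that fell at 0.5, 2 or 6 h, 56 were also lower at 24 h, 7 were not past the test there, and 6 were higher, among them Rsrp1 (1176 ± 341 at 24 h, adjusted p = 0.0392) and Erdr1 (3614 ± 287, adjusted p = 0.00173). Of the 55 lower at 2 h, 52 were lower at 6 h (0.259 expected) and 45 at 24 h (4.83 expected), and of the 66 lower at 6 h, 55 were lower at 24 h (5.79 expected). These expected numbers take no account of the shared 0 h arrays, and unchanged groups simulated against shared controls gave no shared calls in 20 draws, which is no measure of sharing among called probe sets.

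Across the 8140 genes, the log2 changes at 0.5 h and 2 h had a correlation of 0.63, where unchanged groups simulated against the same 2 control arrays gave 0.547, and a covariance of 0.0211 against 0.0267 simulated. For 2 h and 6 h the correlation was 0.59 (0.500 simulated) and the covariance 0.0289 (0.0267). For 6 h and 24 h they were 0.41 (0.500) and 0.0509 (0.0268), and for 2 h and 24 h 0.33 (0.498) and 0.0322 (0.0267). The 0.5 h changes gave 0.26 and 0.0109 with those at 6 h, and 0.11 and 0.00957 with those at 24 h, against 0.547 and 0.0267 simulated for both. With the batch effect built into the simulation the correlations were 0.502 for 0.5 h and 2 h, 0.0226 for 0.5 h and 6 h, 0.502 for 0.5 h and 24 h, 0.324 for 2 h and 6 h, 0.499 for 2 h and 24 h and 0.323 for 6 h and 24 h. The covariances with batch were 0.0096 to 0.0097 for all pairs except 0.5 h and 6 h (0.000671). With batch as a block in the fit the measured correlations were 0.618, 0.563, 0.101, 0.794, 0.329 and 0.493 in the same order. Leaving out 1 array moved the measured values over 0.13 to 0.83, -0.035 to 0.70, -0.040 to 0.36, 0.17 to 0.82, 0.16 to 0.48 and 0.22 to 0.54. The ranges for 0.5 h and 24 h and for 2 h and 24 h lay below both simulated values, and each of the other ranges held both. For these 2 pairs the SE from leaving out 1 array at a time (jackknife) was 0.36 and 0.25. That is too wide to set them apart from the simulated values. Genes are not independent replicates, the 2 control arrays cannot be split, and part of these values may come from the shared controls.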

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

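All tests of explanations in this part were chosen after the results were seen, while the differences between times were planned. The differences below were picked out because the change from 0 h differed between 2 times by a direct test, and the 3' ribosomal RNA control probe set because it rose above its level at 0 h in data outside the comparisons.

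The loss of transcripts from 0.5 h on, such as Snhg3, Gas5 and Taf1d, was weighed first. Values held at the floor shrink the spread and could have produced calls. Both 0 h arrays exceeded every other array by at least 0.5 log2 in 23 probe sets. Any of 25 pairs of arrays of different times, with 1 array from each batch, did so in at most 1. This argues against array noise as the source of those 23. It does not test the spread, and it covers fewer probe sets than the 69 early falls. With only the arrays compared, 0 probe sets passed at 0.5 h (limma, lowest adjusted p = 0.157), with fewer arrays in the fit. A contribution of the floor to the calls stays open. All early falls rest on the same 2 arrays at 0 h, so a trait of those samples could also give the 23. Lower RNA integrity is unlikely, as the highest mean Actb 3' to 5' ratio at 0.5, 2 and 6 h was 1.17 against 1.19 ± 0.0374 at 0 h. In 73.5% of the early falls with a brighter probe set of the same gene (25 of 34), that probe set fell by less than 0.5 times as much, against 34.1% (122 of 358) for falls at 24 h alone (two-sided Fisher exact p = 1.01e-05). Early falls were also larger, with 21 of 34 at least 2-fold at 0.5 h against 238 of 1231 at 24 h. The comparison was not matched for size. Brightness was ranked by the mean over all arrays, which an early fall lowers more than a fall at 24 h alone. Among early falls, a probe set that stayed up was thus more likely to count as brighter than one that fell too. For Ccnt2 the probe set counted as brighter read 300 at 0 h, against 391 for the one that fell. The contrast with falls at 24 h alone is biased by this ranking, so no conclusion is drawn from it. A loss of 1 transcript form, for example an unspliced or alternatively terminated RNA, could account for those 25 falls, although probe sets of a gene are not independent and no form was measured directly. Only 34 of the 69 early falls had a brighter probe set. Snhg3, Snhg4 and Dancr had no other tested probe set and could not be judged this way.

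The rise of histone probe sets was weighed next. The 18S ribosomal RNA control probe set at the 3' end read 401 ± 263 at 0 h, 342 ± 157 at 0.5 h, 10208 ± 222 at 2 h, 10850 ± 251 at 6 h and 1960 ± 1121 at 24 h, and the middle probe set read 253 ± 88.3, 247 ± 163, 5293 ± 743, 8721 ± 109.8 and 1176 ± 397. The 5' probe set read 3682 ± 4041 (825 and 6540 on the 2 arrays), 439 ± 185.6, 5251 ± 2571, 4800.4 ± 357 and 1812 ± 999. More RNA without a poly(A) tail in the labelled material might have raised the histones. From 2 h to 24 h the 7 histone probe sets higher at 6 h changed by a median of 0.91 (SD 0.47, 6 higher and 1 at the floor at both times) while the 18S control changed by -2.50, which argues against this as the whole cause. From 6 h to 24 h all 7 were lower (median -0.50, SD 0.33), as was the 18S control (-2.59), so a share of it in the 6 h values stays open. More cells in S phase at 6 h could also raise histones. The 23 DNA replication genes had a median change of -0.060 (SD 0.19) at that time, so they did not rise with the histones. The mitosis list lay lower then, though without a call with the batch block. The share of cells in S phase was not measured, so this stays open. No biological explanation was tested beyond this.

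The rise of immediate-early and stress genes at 24 h was the last pattern weighed. Embryonic fibroblasts carried over with the conditioned medium could have brought such transcripts, but the highest mean at 24 h among 31 fibroblast marker probe sets was 107, against 100 at 0 h, which argues against them. Lower RNA integrity might contribute: the immediate-early median rise was 1.86 in the 24 h array with a Gapdh 3' to 5' ratio of 0.977, and 1.21 in the array with a ratio of 1.32 (0.882 and 0.941 at 0 h). The larger rise lay in the array of better integrity, but the 2 arrays differ in batch, so this stays open.

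Probe sets that differed numbered 1 between 2 h and 0.5 h, 6 between 6 h and 2 h, 1581 between 24 h and 6 h and 3094 between 24 h and 0.5 h. H2bc22 differed by 1.69 between 6 h and 2 h. Between 24 h and 6 h the differences were 3.10 for Gm6958 on the log2(intensity + 16) scale (at least 9.78-fold, both 6 h arrays at the floor), 2.65 for Gadd45g, 2.56 for Tnfaip3, -2.19 for Utp3, -1.87 for Cpne3 and -1.58 for Kntc1, which returned near its 0 h level. Between 24 h and 0.5 h they were 3.45 for Gadd45g, 3.40 for Ccn2, 3.14 for Serpinb9g, -2.22 for Utp3, -1.91 for Atrx and -1.80 for Cenpf.

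By fry, 13 of the 20 measured lists differed between 24 h and 6 h. Gene lists that differed between 24 h and 6 h by camera had no call with an estimated correlation (adjusted p = 0.132 or more with an estimated correlation for each list). Their median differences were 1.04 for immediate-early genes, 0.96 for NF-kB and cytokine genes, 0.69 for giant cell markers, 0.44 for p53 targets and 0.29 for the unfolded protein and integrated stress response (camera adjusted p = 2.40e-08, 0.000215, 0.0151, 0.000287 and 0.000322). They were -0.70 for trophoblast stem cell markers, -0.46 for DNA replication, -0.70 for mitosis, -0.46 for cholesterol synthesis and -0.29 for ribosome biogenesis (camera adjusted p = 0.0323, 1.71e-05, 1.55e-09, 0.0025 and 0.00149).

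Between 24 h and 0.5 h fry called 14 of the 20 measured lists. The lists called by camera there again had no call with an estimated correlation (adjusted p = 0.132 or more with an estimated correlation). The medians were 1.62 for immediate-early genes, 0.71 for NF-kB and cytokine genes, 1.07 for giant cell markers, 0.65 for p53 targets, 0.52 for the unfolded protein and integrated stress response and 0.33 for heat shock genes (camera adjusted p = 1.55e-09, 0.0008, 0.00668, 0.000271, 0.00231 and 0.049). They were -0.54 for FGF feedback, -0.47 for DNA replication, -0.94 for mitosis, -0.42 for cholesterol synthesis, -0.28 for ribosome biogenesis and -0.71 for epiblast markers (camera adjusted p = 0.0151, 1.12e-05, 7.21e-12, 0.00362, 0.00315 and 0.049).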

How the results depend on the processing

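The batch block, the minimum mean intensity of 200 and the averaged 6 h arrays were added after the data were seen, and the other alternatives were planned. The batches were derived from the values tested, so p-values with the batch block may be too small. None of the 93 named gene values past the test changed direction under any alternative. With the batch block all 93 stayed past the threshold, with either offset or the robust prior 92, without the trend 91, with quantile normalisation 88, with median centring 85, with the mean of a gene's probe sets 78, with array weights 77, without the filter 69, with the 6 h arrays averaged 63, with the minimum mean intensity 64 of the 68 still tested, and with only the arrays compared 11. Leaving out 1 array kept 59 (0 h replicate 2) to 85 (0.5 h replicate 3). A lone sample left at a time was assumed to vary like the other groups. Except where fewer arrays or more tests enter, the cause of a change in the values below was not tested. With 71.6% to 74.9% of values at the floor, low transcripts could not be followed. A stricter filter at the 60th percentile was also 100, removed nothing and was not run, and leaving out 0.5 h replicate 3 is the same as using replicates 1 and 2 of that time.

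Counts of changed probe sets at 0.5, 2, 6 and 24 h were 34, 60, 79 and 2304, those between times (2 and 0.5 h, 6 and 2 h, 24 and 6 h, 24 and 0.5 h) 1, 6, 1581 and 3094, at any time 1444, and shifted lists 3, 0, 2 and 9. Values that moved were as follows. Quantile normalisation gave 4 between 2 and 0.5 h, and median centring 4 there and 22 at 0.5 h. An offset of 64, no trend and the robust prior each gave 0 between 2 and 0.5 h (limma). Without the filter, with more probe sets tested, the counts were 1212 at 24 h, 0, 2, 760 and 1769 between times and 744 at any time, and the shifted lists 9, 4, 9 and 14. Array weights gave 179 at 6 h, 1032 at 24 h, 0 between 2 and 0.5 h and 2025 between 24 and 0.5 h. With only the arrays compared the counts were 0 at each time (limma, 458, 379, 1937 and 2996 at an unadjusted p under 0.05), 0 between 2 and 0.5 h and between 6 and 2 h (326 and 671 at an unadjusted p under 0.05) and 1037 between 24 and 0.5 h, with fewer samples in each fit. A 2-fold threshold gave 21 at 0.5 h, 621 at 24 h, 421 between 24 and 6 h and 707 between 24 and 0.5 h. An estimated correlation left 0 lists at 0.5, 6 and 24 h, and fry 0 at 0.5 and 6 h. At 24 h fry, which does not compare a list with the other genes, called 11 of the 20 measured lists. The batch block gave 67, 143, 248 and 5266 at the 4 times, 7, 10, 3910 and 5820 between times and 4320 at any time. The minimum mean intensity gave 0, 10, 19 and 1531, then 2, 3 and 985 between the first 3 pairs and 887 at any time. The averaged 6 h arrays gave 33 at 2 h, 19 at 6 h, 1491 at 24 h, 0, 1, 213 and 2197 between times, 579 at any time and 3, 0, 2 and 9 shifted lists.

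The replicate numbers are not said to mark a pairing, and of 20 pairs of arrays with the same number 9 had a correlation of residuals over 0.1 (-0.595 to 0.761). With the number as a block, 0 probe sets passed between 2 and 0.5 h, and the similarity of 0.5 and 6 h was -0.035 in place of 0.26.

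Leaving out 1 array gave 20 to 70 changed probe sets at 0.5 h, 22 to 86 at 2 h, 18 to 139 at 6 h and 1099 to 2316 at 24 h, 0 to 1 between 2 and 0.5 h, 1 to 24 between 6 and 2 h, 219 to 1585 between 24 and 6 h, 2005 to 3125 between 24 and 0.5 h and 585 to 1359 at any time. Shifted lists ranged from 0 to 4, 0 to 2, 2 to 3 and 9 to 10. The similarity of 0.5 h with 2, 6 and 24 h ranged from 0.13 to 0.83, -0.035 to 0.70 and -0.040 to 0.36, that of 2 h with 6 and 24 h from 0.17 to 0.82 and 0.16 to 0.48, and that of 6 and 24 h from 0.22 to 0.54.

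Genes that changed sign were panel genes not past the test. At 0.5 h, Slc6a6 (-0.05) had 0.012 after median centring, 0.0038 with the replicate block and 0.031 with the mean of its probe sets, Ddit3 (-0.04) 0.021 and Id2 (-0.04) 0.017 after median centring, Id2 0.10 with the mean of its probe sets, Egr1 (0.05) -0.10 with the batch block, and Hand1 (0.01) -0.13 with array weights and -0.22 with the replicate block. At 2 h, Ddit3 (-0.01) had 0.015 and 0.092 and Hand1 (-0.01) 0.093 and 0.091 after quantile normalisation and median centring. At 6 h, Cdkn1a (-0.08) had 0.26 and Id2 (-0.10) 0.020 with the mean of their probe sets, and Cdx2 (0.29) -0.16 and Hand1 (0.28) -0.055 with the batch block. Hand1 at 24 h (0.09) had -0.18 with the mean of its probe sets. Leaving out 1 array gave, at 0.5 h, Slc6a6 -0.089 to 0.0038, Fos -0.24 to 0.10, Egr1 -0.34 to 0.45, Ddit3 -0.080 to 0, Cdx2 -0.88 to 0.32, Id2 -0.13 to 0.062 and Hand1 -0.31 to 0.33. At 2 h the ranges were Fos -0.059 to 0.29, Egr1 -0.21 to 0.58, Cdkn1a -0.40 to 0.042, Ddit3 -0.046 to 0.033, Cdx2 -0.55 to 0.65 and Hand1 -0.35 to 0.33. At 6 h they were Egr1 -0.089 to 0.70, Cdkn1a -0.23 to 0.069, Cdx2 -0.31 to 0.89, Id2 -0.12 to -0.075 and Hand1 -0.037 to 0.60, and at 24 h Hand1 -0.27 to 0.44.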

Other observations

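The gene families in this part were all chosen after the data were seen, and their tests are exploratory. At 24 h, some probe sets of the prolactin, Serpinb9 and keratin families rose, though none of these families was shifted with an estimated correlation. All 3 tested probe sets of the prolactin family, hormones of giant cells and spongiotrophoblast, rose (median 1.66, adjusted p = 0.274 with an estimated correlation). Those of Prl7a1 and Krt10 lay at the floor at every time before 24 h and were tested only because both 24 h arrays exceeded it. Family members that stayed at the floor were not counted, so the shares that rose are partly fixed by the filter. Of 6 probe sets of the Serpinb9 cluster, protease inhibitor genes of which several are expressed in placenta, 5 rose (median 1.97, adjusted p = 0.158 with an estimated correlation), with Serpinb9g from 269 ± 127 to 1673 ± 377 and Serpinb9b from 409 ± 38.9 to 1546 ± 581 (adjusted p = 0.00948 and 0.0235). Of 12 keratin probe sets 4 rose. They were those of Krt14, Krt19, Krt42 and Krt10, at 1.48, 1.06, 0.97 and 0.75 (adjusted p = 0.00628, 0.00693, 0.00952 and 0.000965). Probe sets of Krt7, Krt8 and Krt18 did not pass the test (adjusted p = 0.117 to 0.331). The family had a median of 0.41 (adjusted p = 0.126 with an estimated correlation). Of 5 Gadd45 probe sets, 3 of them for Gadd45b, 4 rose (median 2.24, adjusted p = 0.0175 with an estimated correlation), and of 27 Klf probe sets 8 rose (median 0.43, adjusted p = 0.388 with an estimated correlation).

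The 18 probe sets of small nucleolar RNA host genes had medians of -0.51, -0.84, -0.53 and -0.14 at 0.5, 2, 6 and 24 h (adjusted p = 0.0175, 0.011, 0.0175 and 0.324 with an estimated correlation), and 5, 6, 6 and 6 of them fell. Several were probe sets of the same gene, Gas5 or Snhg1, so they are not independent members. While 1 Snhg1 probe set fell, the brightest changed by -0.59, -0.77 and -0.45 at 0.5, 2 and 6 h, none past the test. Of the 23 histone probe sets 4 rose at 2 h (adjusted p = 0.175 with an estimated correlation). Their median was 0.10 at 6 h (0.034 with the batch block), when 7 rose, and 0.49 at 24 h, when 9 rose and 1 fell (adjusted p = 0.125 and 0.183 with an estimated correlation). Of 149 probe sets of RNA-binding proteins of the Srsf, Rbm and Hnrnp families, 25 fell and 3 rose at 24 h (median -0.27, adjusted p = 0.324 with an estimated correlation). Of 168 ribosomal protein probe sets 7 fell and 1 rose (median -0.07, adjusted p = 0.777 with an estimated correlation), and of 206 Zfp and Zbtb zinc finger probe sets 18 fell and 10 rose (median -0.07, adjusted p = 0.917 with an estimated correlation).

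The 18S control probe set at the 5' end read 6540 in 0 h replicate 2 and 825 in 0 h replicate 1, where the 3' probe set read 215 in replicate 2.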
